A study of Mus musculus with 3 samples.

How the data were processed

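The samples were 3 polyA-selected RNA-seq libraries from activated regulatory T cells of a male mouse aged 9 weeks. Per the labels, the libraries were technical replicates 1, 2 and 3 of 1 biosample from 1 donor, with fragmentation by shearing. The labels do not say how the cells were activated or sorted. No second group was present, so no comparison between conditions was made. Every SD and n = 3 below is over libraries of the same biosample and is therefore technical.

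Each library had a larger gene table, a transcript table and a smaller gene table. Per the file headers and the sample notes, the larger gene table and the transcript table were made by the authors on mm10 with GENCODE M21, and hold expected counts, TPM and FPKM deposited per gene or transcript. The aligner and the quantification program are not given in the sources used here, although the column names are those that RSEM writes. Expected counts split reads that match several genes, so they need not be whole. TPM and FPKM were deposited already corrected for effective length. In the row of the phiX174 genome, length exceeded effective length by 49 bases, as reads of 50 bases give. Whether the counting used strand is not given in the sources used here, so reads of overlapping and antisense genes may be mixed. The smaller gene table deposited by the authors holds whole-number counts for 22457 genes on mm10 with GENCODE M4, from a separate alignment per the sample notes. Of these, 22195 matched a gene of the larger table by identifier. From the values, its counts levelled off in abundant genes, with medians of 0.993, 1.00 and 1.01 per base of transcript length in genes with at least 10000 expected counts. Of 10544 detected genes, 842, 833 and 991 exceeded 1 count per base in libraries 1, 2 and 3, and the highest had 5.88 per base. Over the merged exons of all transcripts, 5, 4 and 4 genes exceeded 2 per base, none longer than 54 bases. None exceeded the start positions that reads touching those exons have on both strands, and the highest stood at 92.4% of them. The table was therefore read as counting distinct read positions on both strands, which no header or label states. Some genes with shared reads had far fewer counts there than levelling off gives. In library 1, Pgam1 had 3 against 4614 expected counts and Cycs 1 against 679. How the smaller table treats shared reads is not given in the sources used here. Its differences from the larger table may therefore reflect shared reads as well as levelling off.

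The larger gene table had 81881 rows, of which 55536 matched an annotated gene. The other rows were 26248 with numeric identifiers (median length 73 bases), 96 spike-in controls with 0 counts and the phiX174 genome. These rows stayed out of library sizes and tests and held 0.125%, 0.182% and 0.155% of the counts in libraries 1, 2 and 3. Expected counts summed to 31445344, 32612609 and 37259281 over all rows of libraries 1, 2 and 3. The smaller tables summed to 8827129, 8758421 and 9555924 counts. Where a gene was at 0, the floor was taken as the TPM that 3 counts would give in a library. Reads without molecular identifiers are not independent molecules, so floors cover counting error only and the chi-square test compares read counts, not molecules.

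A gene was called detected with a TPM of at least 1 in all 3 libraries. Expected counts were rounded to whole numbers for the count models. The common biological coefficient of variation was the square root of the common dispersion from edgeR 4.0.16 with TMM normalization, an intercept-only design and a summed count of at least 30. Each gene was also tested for equal shares over the 3 libraries with a chi-square test on counts (2 degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. Fisher's exact test, two-sided, compared 27 of the 28 fixed lists, and the receptor segments, with all tested genes. A list needed at least 3 tested members, so the X inactivation list, with 2 genes, was left out. List levels were the median TPM over members, set against 10000 random lists of protein-coding genes of the same size. The random lists were not matched on expression and included undetected genes. The 7 list comparisons used two-sided permutation tests across genes of mean log2(TPM + 1), with a pseudocount of 1 and 100000 resamples, or all arrangements where a list had fewer than 10 members. Genes are not independent replicates, so these p-values describe the lists only. For the 15 gene pairs, a log2 ratio was called larger than the spread when its 3 values had the same sign and their mean exceeded 2 SD. An exact sign-flip test of 3 libraries cannot go below 0.25. Isoform shares were each transcript's part of its gene's summed TPM for 10 genes, named from 5%. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6 were used.

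The 28 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule names both genes of each pair, the isoform genes, the 4 highest members and the lowest member of each list, and all members of lists with 8 or fewer. It also names the 15 most abundant protein-coding genes other than mitochondrially encoded and ribosomal protein genes, and the 10 genes with the greatest variation in excess of counting noise among varying genes with a mean count of at least 100. In a list over-represented among varying genes it adds up to 6 members, and the 5 lists of Treg and T cell state could be named in full. Some of the genes this rule takes are not reported here. Alternatives covered normalization, count and TPM thresholds, the smaller table, FPKM, CPM with no length correction, the pseudocount, medians and each library left out. Alternatives added after the data were seen divided the chi-square by the overdispersion shared by all genes, kept only members whose expected counts were whole within 0.005, or left out each library in turn in the test of lists among varying genes.

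The steps were tested on simulated data. For the chi-square test over 15945 genes, Poisson counts were drawn from the real means, with 200 genes changed in 1 library. The test recovered 49.2% of 1.2-fold, 74.6% of 1.5-fold and 87.1% of 2-fold changes, and called 0.0445% of unchanged genes. The real counts had a median chi-square of 8.87 times its Poisson median. These rates therefore hold for counting noise alone and do not carry over to the real libraries. With a simulated coefficient of variation of 19.8% in every gene, edgeR returned 19.8%. In the real counts its trend fell from 59.3% in the lowest quartile of mean count to 6.45% in the highest. Of 300 random pairs of lists, 2.33% had a permutation p under 0.05.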

Results

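Polyadenylated RNA was sequenced from activated regulatory T cells (Treg cells, the CD4 T cells that restrain immune responses through the transcription factor Foxp3). The series held 3 technical libraries of 1 biosample from a male mouse of 9 weeks, with 31445344, 32612609 and 37259281 expected counts in libraries 1, 2 and 3. The labels gave a single group, so the values below are transcript levels, comparisons between genes within these cells, and the spread between libraries. All means are TPM ± SD with n = 3 libraries unless stated, and the SD is technical.

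Among protein-coding genes other than mitochondrially encoded and ribosomal protein genes, Tmsb4x, which encodes an actin-sequestering peptide, was the most abundant at 18625 ± 602 TPM. The MHC class I genes H2-K1 (10790 ± 465), B2m (8376 ± 496) and H2-D1 (5633 ± 193) followed, and Tmsb10 reached 4692 ± 178. The actin regulator genes Pfn1 (4829 ± 41.1), Cfl1 (3727 ± 50.9) and Coro1a (2939 ± 109) and the actin genes Actb (3043 ± 118) and Actg1 (2989 ± 19.4) were also among the 15 most abundant. The remaining genes of the 15 were Cd52 (3536 ± 68.8), Ly6e (3486 ± 22.3), Ppia (3403 ± 54.0), Shisa5 (3402 ± 89.8) and Eef1a1 (3181 ± 71.1). Together the 15 genes took 5.16% ± 0.0507 of counts (SD, n = 3). Of 55536 annotated genes, 12629 were detected in all 3 libraries, among them 10429 of 22028 protein-coding genes. Several of the 15, such as H2-K1, H2-D1, Actb and Eef1a1, shared reads with similar genes, so their levels are less certain.

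All 16 members of the Treg core list were detected, and 13 exceeded 100 TPM. Foxp3 (ENSMUSG00000039521.13, mm10 chromosome X, 7573644 to 7595245, plus strand) stood at 135 ± 2.65 TPM. The interleukin 2 receptor chains Il2rb (1032 ± 32.5) and Il2ra (317 ± 14.3; chromosome 2, 11642807 to 11693193, plus strand) were abundant, as were the costimulatory receptors Tnfrsf4 (951 ± 21.4) and Tnfrsf18 (873 ± 5.72). The inhibitory receptor gene Ctla4 (chromosome 1, 60887000 to 60915832, plus strand) reached 389 ± 5.70, and Ikzf2, which encodes Helios (chromosome 1, 69531214 to 69687245, minus strand), 389 ± 26.3. Capg (967 ± 32.3) and Izumo1r (609 ± 18.9) were also high, and the lowest members were Entpd1 (70.3 ± 3.54), Ikzf4 (65.7 ± 2.11) and Gpr83 (65.6 ± 2.17). The median of the list was 251 TPM, above all of the 10000 random lists of its size (percentile 100), which were not matched on expression.

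**Figure D1:**
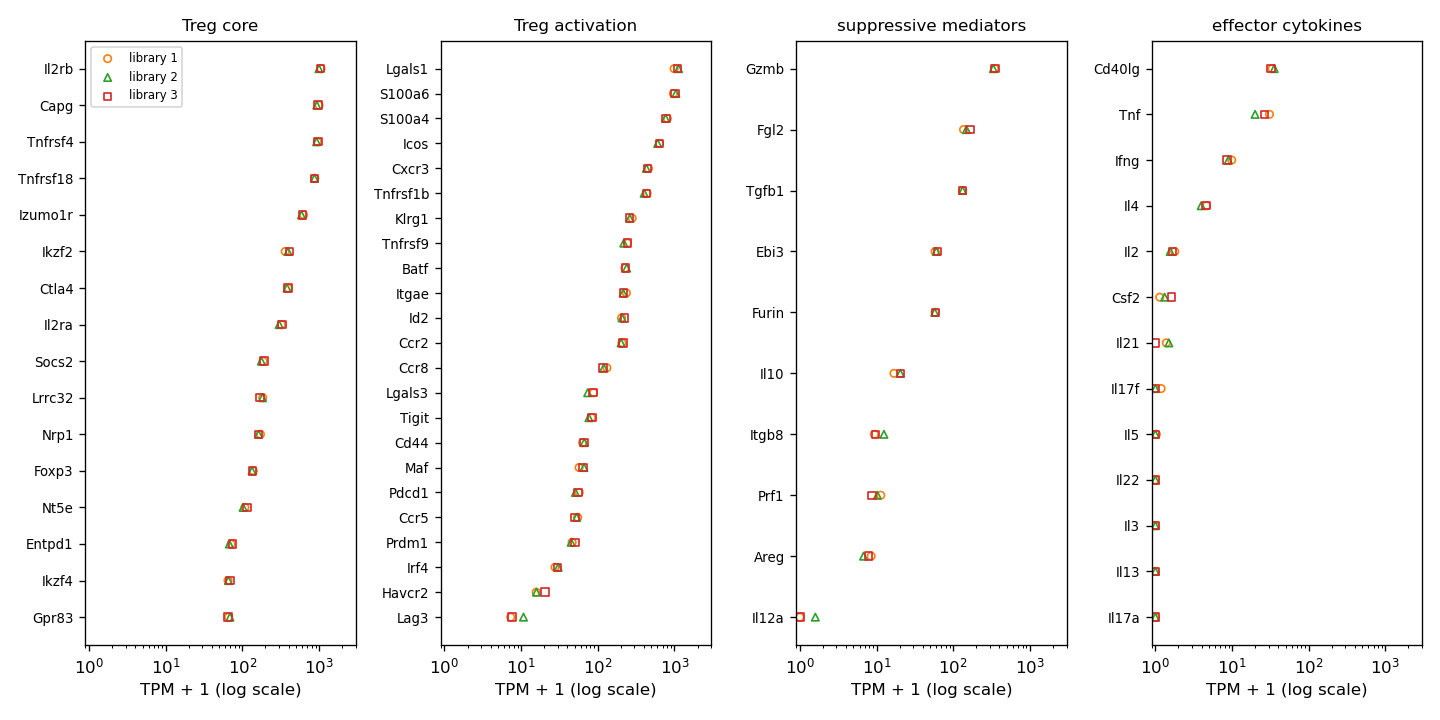
TPM + 1 on a log scale for each member of 4 gene lists, with 1 symbol per library (circle, library 1; triangle, library 2; square, library 3) and genes ordered by mean. All 16 Treg core genes and all 23 Treg activation genes lay above 1 TPM in every library, whereas 4 of 13 effector cytokines did.

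Genes of activated Treg cells and genes of naive or resting T cells were both abundant. All 23 activation members were detected, led by Lgals1 (1071 ± 74.3), S100a6 (1008 ± 37.9), S100a4 (782 ± 20.9) and the costimulatory receptor gene Icos (625 ± 19.6). The chemokine receptor gene Cxcr3 (443 ± 14.0), Tnfrsf1b (424 ± 19.7), Klrg1 (266 ± 11.97) and Tnfrsf9 (234 ± 14.7) were also high, whereas Irf4 (28.3 ± 1.48), Havcr2 (16.4 ± 2.77) and Lag3 (7.57 ± 1.89) were low. All 14 naive and resting members were detected as well, including the lymphocyte trafficking genes S1pr1 (322 ± 5.59) and Ccr7 (244 ± 18.0) and the transcription factor genes Klf2 (437 ± 7.11), Tcf7 (260 ± 12.1) and Lef1 (189 ± 2.72). The lists had medians of 206 and 177 TPM. Their mean log2(TPM + 1) differed by -0.07 ± 0.03 (SD, n = 3, activation minus naive; permutation p = 0.908, adjusted p = 0.908 over 7 comparisons), by 0.22 in medians and by -0.61 in the smaller table, neither past the threshold.

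Treg core genes, taken as a list, exceeded the transcription factor genes of other helper lineages. Among the latter, Gata3 (120 ± 2.90), the Th2 regulator, and Stat4 (115 ± 3.26) were highest. Rora (58.9 ± 2.98), the Th1 regulator Tbx21 (42.3 ± 2.80) and Ahr (27.8 ± 2.02) were intermediate. Bcl6 (7.06 ± 0.623) and Eomes (1.85 ± 0.489) were low. The core list, however, holds many receptor genes, whereas the other list holds transcription factor genes only. The difference between the lists therefore cannot be assigned to lineage rather than gene class. Of the core transcription factor genes, Ikzf2 (389 TPM) lay above Gata3, Foxp3 (135) close to it and Ikzf4 (65.7) below it. In the smaller table Ikzf2, with 2032, 2007 and 2180 counts, lay below Gata3, with 2096, 2056 and 2250. Of the Ikzf2 TPM, 67.4% fell on a retained intron transcript, and 46.0% of the Foxp3 TPM on a transcript annotated as subject to nonsense-mediated decay. The order of these genes by TPM therefore depends on the measure. The core list was higher by 3.54 ± 0.02 on the log2 scale, in each of 3 libraries (SD, n = 3; exact permutation p = 0.000163, adjusted p = 0.000381), and by 1.56 in the smaller table (exact permutation adjusted p = 0.0356). Foxp3 exceeded Bcl6 by 4.26 ± 0.14 log2 units and Tbx21 by 1.67 ± 0.10 (SD, n = 3), against 2.64 and 0.76 in the smaller table. Foxp3 and Gata3 were close, with a log2 ratio of 0.17 ± 0.05 that became -0.71 in CPM with no length correction and -0.09 in the smaller table.

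Genes for suppressive mediators were expressed at higher levels than effector cytokine genes. The cytotoxic protease gene Gzmb (342 ± 8.80), Fgl2 (149 ± 15.2) and Tgfb1 (131 ± 0.260) led the first list, followed by Ebi3 (59.2 ± 2.27), Furin (56.9 ± 0.542) and Il10 (18.3 ± 2.10). Itgb8 (9.51 ± 1.70), Prf1 (9.08 ± 1.33) and Areg (6.68 ± 0.871) were lower, and Il12a, which did not reach 1 TPM, had 15 counts in library 2 and 0 in the other two. Among effector cytokines, Cd40lg (32.6 ± 1.73), Tnf (24.8 ± 5.43), Ifng (8.13 ± 0.704) and Il4 (3.39 ± 0.375) passed 1 TPM in every library. Il13, Il17a, Il22 and Il3 had 0 counts in all 3 libraries, which allowed mean levels of up to 0.123, 0.127, 0.134 and 0.246 TPM. The difference between the lists was 3.58 ± 0.09 on the log2 scale (SD, n = 3; permutation p = 0.00148, adjusted p = 0.00259, in the same direction in 3 of 3 libraries). It lost significance among the 9 and 4 members with a TPM of at least 1, at 1.61 (exact permutation adjusted p = 0.227), so it rested in part on cytokine genes near 0. It also did so among the 6 and 10 members with no shared reads, at 2.29 (exact permutation adjusted p = 0.0893).

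Further gene pairs set surface and effector genes against each other. Il2ra exceeded Il7r (107 ± 1.75) by 1.57 ± 0.07 log2 units, Ctla4 exceeded Cd28 (147 ± 2.60) by 1.40 ± 0.04 and Icos exceeded Cd28 by 2.08 ± 0.07 (SD, n = 3). Ikzf2 exceeded Ikzf4 by 2.57 ± 0.06, Gzmb exceeded Prf1 by 5.24 ± 0.23 and Cxcr3 exceeded Ccr6 (20.6 ± 0.790) by 4.43 ± 0.06. Il10 exceeded Il2 (0.673 ± 0.115) by 4.77 ± 0.40 and Tgfb1 exceeded Ifng by 4.02 ± 0.12. Prdm1 (46.2 ± 2.70) lay below Tcf7, with a log2 ratio of -2.50 ± 0.11. Every ratio given here exceeded 2 SD. That SD is between libraries and leaves out errors of length or read assignment that the libraries share. With no length correction Ctla4/Cd28 became 0.29, Icos/Cd28 1.203 and Prdm1/Tcf7 -1.39. The smaller table levels off in abundant genes and has few counts for some genes with shared reads. In it, 12 of the 15 pairs tested exceeded the spread, 2 of them in the other direction. There Il2ra/Il7r became -0.09, Ctla4/Cd28 0.37, Icos/Cd28 0.40, Gzmb/Prf1 2.35 and Cxcr3/Ccr6 2.51, while Ikzf2/Ikzf4 at 0.06 and Prdm1/Tcf7 at 0.20 no longer exceeded the spread. Il10/Il2 had no value there, since Il2 had 0 counts in all 3 libraries of that table, and its expected counts shared reads with other genes, so that ratio is uncertain.

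Markers placed the libraries among T cells. The T cell genes Cd2 (1322 ± 27.2), Cd3e (1274 ± 39.0), Cd3g (1210 ± 10.1) and Lck (1161 ± 9.21) were abundant, with Cd4 at 394 ± 15.9 and Thy1, the lowest of the list, at 110 ± 1.71. B cell genes were low, with Cd79b at 29.3 ± 3.95, Cd79a at 8.04 ± 2.93, Cd22 at 5.66 ± 1.18, Ms4a1 at 2.69 ± 0.878 and Pax5 at 0.0867 ± 0.0252. The pan T cell list exceeded the B cell list by 7.11 ± 0.10 log2 units and the macrophage and monocyte list by 5.87 ± 0.10 (SD, n = 3; permutation p = 2e-05, the smallest that the resamples can give, adjusted p = 7e-05 for both). In the smaller table the differences were 5.05 and 3.68, with the same adjusted p. Cd74 (327 ± 21.2) was the exception in the macrophage list, in which Lyz2 (24.9 ± 6.03), C1qb (10.1 ± 2.55), C1qc (8.23 ± 0.949) and Cd14 (0.273 ± 0.291) were far lower. Cd8a stood at 1.64 ± 0.594 against Cd4, a log2 ratio of 7.97 ± 0.48, whereas Cd8b1 reached 21.4 ± 0.893 and Nkg7 335 ± 4.16 in the list of CD8 and NK genes. In that list Gzma stood at 2.53 ± 0.257 and Klra8 had 0 counts, which allowed up to 0.126 TPM.

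Other lineages gave low levels with some exceptions. The gamma delta T cell genes Tcrg-C1 (9.52 ± 1.18), Tcrg-C2 (7.13 ± 0.287) and Trdc (4.15 ± 0.199) were low, and Sox13 (0.0567 ± 0.0981) and Cd163l1 (0.0533 ± 0.0924) were near 0. The MHC class II genes H2-Ab1 (31.8 ± 8.53), H2-Eb1 (25.5 ± 1.69) and H2-Aa (24.5 ± 2.29) led the dendritic cell list, with Zbtb46 at 1.83 ± 0.427 and Flt3 at 0.0867 ± 0.0902. The haemoglobin genes Hbb-bs (265 ± 47.7), Hba-a2 (259 ± 43.9), Hba-a1 (164 ± 30.3) and Hbb-bt (54.3 ± 8.90) were present, whereas the platelet gene Ppbp (0.143 ± 0.169) was near 0. Pecam1 (82.7 ± 2.38) stood alone in the stroma and endothelium list, above Col1a1 (0.577 ± 0.140), Col1a2 (0.243 ± 0.244), Acta2 (0.183 ± 0.200) and Pdgfrb (0.00667 ± 0.0115). In the plasma cell list Ighm reached 1630 ± 72.8 and Igkc 320 ± 57.0, Igha 14.6 ± 19.2, Jchain 13.7 ± 5.72, Mzb1 2.59 ± 1.21 and Sdc1 0.160 ± 0.131, and Tnfrsf17 had 0 counts, which allowed up to 0.186 TPM. None of the 12 granulocyte and mast cell genes reached 1 TPM in all 3 libraries. S100a8 (2.65 ± 4.42), S100a9 (2.05 ± 3.22), Ngp (1.86 ± 2.45) and Ly6g (0.807 ± 0.603) were the highest and Ms4a2 (0.00667 ± 0.0115) the lowest.

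Replication genes were expressed above mitotic genes. The helicase genes Mcm6 (190 ± 4.96), Mcm4 (82.9 ± 2.09) and Mcm5 (71.7 ± 1.95) and the sliding clamp gene Pcna (149 ± 12.8) led the S phase list, which ended at Cdc6 (11.2 ± 0.909). Birc5 (50.4 ± 4.52), Top2a (45.7 ± 2.36), Ccnb2 (43.3 ± 2.62) and Mki67 (26.8 ± 1.28) led the G2 and mitosis list, which ended at Bub1 (2.21 ± 0.662). The S phase list was higher by 1.59 ± 0.06 log2 units in each of 3 libraries (SD, n = 3; permutation p = 0.00222, adjusted p = 0.00311). The difference lost significance in the smaller table, at 0.90 (permutation adjusted p = 0.134), and among the 3 and 6 members with no shared reads, at 2.04 (exact permutation adjusted p = 0.0893).

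Genes of glycolysis and of oxidative phosphorylation were both abundant. Ldha (1252 ± 17.2), Eno1 (872 ± 27.4), Pkm (836 ± 24.4) and Aldoa (412 ± 9.11) led the first list, in which the hexokinase gene Hk2 (1.93 ± 0.531) was lowest. Atp5b (989 ± 51.7), Cox4i1 (746 ± 36.1), Atp5a1 (542 ± 5.75) and Cox6c (519 ± 27.5) led the second, in which Cycs (16.9 ± 2.63) was lowest. The lists differed by -0.59 ± 0.07 log2 units (SD, n = 3, glycolysis minus oxidative phosphorylation; permutation p = 0.359, adjusted p = 0.419), and by 0.47 with no length correction. Several of these genes, Ldha, Eno1 and Pkm among them, shared reads with similar genes.

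In the remaining lists, the interferon response genes Zbp1 (269 ± 5.01), Irf9 (175 ± 8.48) and Rtp4 (144 ± 2.80) were among the highest and Rsad2 (7.81 ± 1.96) lowest. The integrin gene Itgb7 (1607 ± 63.6), Selplg (1267 ± 46.9), Itgb1 (441 ± 5.59) and Itgal (215 ± 14.8) led the homing receptors, and Cxcr4 (5.58 ± 0.211) was lowest. Jund (741 ± 8.41), Junb (334 ± 14.9), Zfp36 (162 ± 7.96) and Ier2 (161 ± 5.13) led the immediate early genes, and Atf3 (0.127 ± 0.110) was lowest. Cd27 (452 ± 6.94), Vsir (214 ± 2.53) and Cd96 (113 ± 9.29) accompanied Cd28 in the checkpoint list, which ended at Cd80 (6.49 ± 0.0755). Among cholesterol synthesis genes, Srebf2 (109 ± 4.32), Fdps (55.3 ± 3.96) and Dhcr7 (36.0 ± 0.852) were among the highest. Among RNAs without poly(A) tails, Rn7s1 and Rn7s2 each stood at 191 ± 22.5 and shared their reads, Rn7sk at 87.8 ± 16.5, Rpph1 at 5.88 ± 1.96, Terc at 1.57 ± 0.423 and Rmrp at 0.593 ± 1.03. Of the 28 lists, 16 had medians above the 95th percentile of random lists. The random lists also drew on undetected genes, since 10429 of 22028 protein-coding genes were detected. Passing this mark therefore shows that a list was expressed, not that its level was particular to these cells.

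Y-linked genes were compared with the label male. Eif2s3y (104 ± 4.20), Ddx3y (67.5 ± 5.15), Kdm5d (31.3 ± 2.32) and Uty (27.9 ± 2.64) were detected in all libraries. Xist (0.0967 ± 0.159) and Tsix (0.0867 ± 0.142), transcribed from the X inactivation centre, were near 0.

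The transcript tables gave the isoforms behind these levels. Ctla4-201 held 99.2% ± 0.225 of Ctla4, Pkm-201 94.5% ± 0.430 of Pkm, Prdm1-201 77.8% ± 1.81 of Prdm1 and Il2ra-201 73.6% ± 0.574 of Il2ra (SD, n = 3). Tigit (79.9 ± 3.84 TPM) had the single transcript Tigit-201. Ptprc, which encodes the leukocyte phosphatase CD45 (1079 ± 36.5 TPM), was led by Ptprc-203 (43.9% ± 1.54) and Ptprc-204 (22.7% ± 0.181). Cd44 (64.2 ± 1.58 TPM) was divided between Cd44-203 (57.7% ± 3.13) and Cd44-207 (35.4% ± 1.60), and Foxp1 (165 ± 7.23 TPM) was led by Foxp1-228 (22.2% ± 2.73). For Foxp3, 46.0% ± 2.52 fell on Foxp3-207, annotated as subject to nonsense-mediated decay, and 27.4% ± 3.35 on Foxp3-206. For Ikzf2, 67.4% ± 3.19 fell on the retained intron transcript Ikzf2-205 and 17.3% ± 0.178 on Ikzf2-201. By expected counts, which weight long transcripts more, the leading transcript changed in 3 of these genes. The Ikzf2 shares were then 40.1% and 51.1%, Cd44-203 held 45.3% against 49.6% for Cd44-207, and Foxp1-228 held 20.9% against 29.8% for Foxp1-204. Reads of 50 bases seldom span several exon junctions, which limits how such shares can be resolved.

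Read counts differed between the 3 libraries by more than counting noise, in a test that treats each read as independent. Of 15945 genes tested, 10471 (65.7%) varied in the chi-square test after adjustment, 5953 of them by at least 10% in excess of counting noise. Only 328 varied once the chi-square was divided by the overdispersion shared by all genes, and 3849 varied in the smaller table. The common biological coefficient of variation from edgeR was 19.8%, and was 15.2% without library 2. It was 28.2% with no count filter, 11.7% from a summed count of 300, 8.87% in the smaller table and 8.05% as the DESeq2 gene-wise median. Variation was large in scarce genes and small in abundant ones: the median excess over counting noise was 41.9% at a median mean count of 14, and 3.90% at 6800. Over the 6387 genes with a mean count of at least 1000 it was 5.05%. The number of varying genes was 5995 without library 2 and 6741 without library 3.

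**Figure D2:**
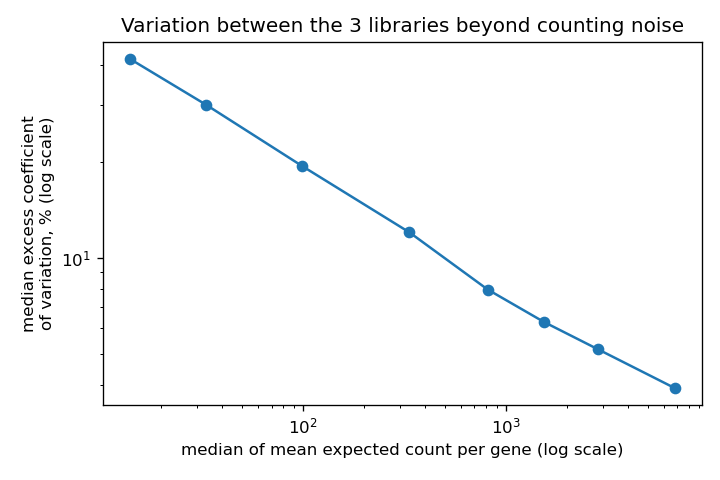
Median coefficient of variation between the 3 libraries in excess of counting noise (percent, log scale) against the median of the mean expected count (log scale), for 8 bins of equal size over 15945 genes. The excess was 41.9% in the lowest bin and 3.90% in the highest.

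Immunoglobulin segments were over-represented among varying genes, whereas the calls of T cell receptor segments and of the fixed lists depended on how variation was defined. Of 54 immunoglobulin segments, 50 varied (50 adjusted over the list alone; odds ratio 6.56, Fisher's exact test, adjusted p = 7.11e-05). Receptor segments can vary together and share reads, so they are not independent, and p-values for segments describe these groups only. Library 2 had the fewest counts on Ighv segments, with 559, 304 and 559 in libraries 1, 2 and 3, and on Igkv segments, with 967, 563 and 959. It also had the fewest in the B cell list (1838, 1402 and 1773), the dendritic cell list (2167, 1654 and 2253) and the erythroid and platelet list (9550, 7197 and 9295). The same held for effector cytokines (1958, 1750 and 2098) and for G2 and mitosis genes (15160, 15000 and 17766). It also held for the plasma cell, macrophage and monocyte, and granulocyte and mast cell lists. Library 2 was not lowest in the other lists, among them CD8 and NK genes (5011, 5205 and 5697) and pan T cell genes (249077, 252233 and 289863). These counts were not scaled for depth. The median TPM of the pan T cell list was lowest in library 2, at 600, 544 and 591 in libraries 1, 2 and 3. Without library 2, 41 of 49 immunoglobulin segments varied (odds ratio 7.55, Fisher's exact test, adjusted p = 1.3e-08). Of 174 T cell receptor segments, 54 varied (34 adjusted over the list alone; odds ratio 0.231, Fisher's exact test, adjusted p = 2.84e-19). Treg activation was the only fixed list past the threshold, with 22 of 23 members varying (22 adjusted over the list alone; odds ratio 11.5, Fisher's exact test, adjusted p = 0.0137). Its smallest p-values belonged to Tnfrsf1b, Maf, Tnfrsf9, Itgae, Prdm1 and Lgals1. The call of that list was lost without library 1 (adjusted p = 1) and without library 2 (adjusted p = 0.179), while both segment calls held without each library. Against genes matched on mean count the Treg activation call was also lost (permutation adjusted p = 0.565). Both segment calls held there (permutation adjusted p = 0.0029 for both, from the smallest p that the resamples can give). Among the 328 genes that varied beyond the shared overdispersion, immunoglobulin segments stayed over-represented with 16 genes (odds ratio 21.02, Fisher's exact test, adjusted p = 2.15e-13). There the T cell receptor call was lost and turned direction, with 5 genes (odds ratio 1.41, adjusted p = 0.853), and the Treg activation call was lost (adjusted p = 0.389). Plasma cell genes, 4 of 5 tested (adjusted p = 1.25e-05), and granulocyte and mast cell genes, 2 of 5 tested (adjusted p = 0.0391), were over-represented there. The plasma cell list includes the immunoglobulin genes Igha, Ighm and Igkc, so its call is not separate from that of the immunoglobulin segments.

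The 10 genes with the greatest excess variation were Gm26825, Gm6565, Trav7-2, Zc3h11a (ENSMUSG00000116275.1), Igha, Igkv1-110, Iglc3, Trav12n-3, Gm10163 and Gm47248. Igha (mm10 chromosome 12, 113254830 to 113260236, minus strand), the constant region of IgA, had 82, 126 and 964 expected counts in libraries 1, 2 and 3. The other 9 shared reads with similar genes, so their counts are uncertain. Gm26825 had 794 counts in library 1 and 0 in the other two.

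The 2 gene tables ranked genes alike over the full range and less so among expressed genes. Spearman's rho across 22195 genes was 0.948, 0.946 and 0.949 in libraries 1, 2 and 3, and 0.837, 0.831 and 0.823 over the 10544 genes detected. Genes are not independent replicates. For Tmsb4x, 229302 expected counts in library 1 stood against 548 in the smaller table. Genes with at least 10000 expected counts had a median of 13.2%, 12.9% and 13.0% of them in the smaller table, whereas genes with 100 to 1000 had 54.3%, 53.2% and 53.4%. Some less abundant genes with shared reads were also low there, such as Cycs, with 1 against 679 expected counts in library 1.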

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

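For gene count variation, the tests of a uniform expression difference and of few starting molecules were chosen after the result was seen, as were the tests of repeated and of shared reads for granulocyte genes, the leaving out of Mmp9 and the test of shared reads for Ighm.

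Reads of the phiX174 genome, a sequencing control, made up 0.147% ± 0.0284 of expected counts (SD, n = 3), above the limit that a count of 0 allows. Rows with numeric identifiers, whose identity is not given in the sources used here, held 2412 ± 199 expected counts per library (SD, n = 3), also above that limit.

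Gene counts varied between libraries of 1 biosample by more than counting noise. Copies made after shearing did not account for all of it: over 2496 genes with fewer than 0.05 smaller-table counts per base, the median chi-square was 4.26 times its Poisson median, against 8.76 times in expected counts, if that table counts distinct positions. Shared reads did not either, since 7775 genes with whole counts gave 8.92. A uniform difference in expression as the only source was argued against by a slope of log excess on log mean of -0.786 ± 0.0140 (SE). That slope cannot tell whether a smaller uniform difference was added to sampling noise. Few starting molecules, amplified before shearing, may contribute, as the slope in the smaller table was -0.934 ± 0.0507 (SE), near the -1 that sampling of molecules gives, on the same reading of that table. No biological explanation was tested, since the design names none.

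Granulocyte genes were higher in library 1 than in the other two, such as S100a8 with 66, 0 and 2 counts and Ngp with 107, 11 and 12 in libraries 1, 2 and 3, whereas Ly6g, with 20, 2 and 15 counts, was level in libraries 1 and 3 at 1.15 and 1.16 TPM. The list's smaller-table count in library 1 was 6.96 times the mean of the other two, against repeated reads made after shearing if that table counts distinct positions, and 9 members highest there by depth-scaled expected counts had whole counts, against shared reads. Granulocytes among the cells of library 1 were tested on 17 neutrophil genes outside the list, whose summed count there was 1.07 times the mean of the other two, but Mmp9, at 33.7 to 38.8 TPM, held 93.7% of those counts and could hide a change, and without it the ratio was 2.02, which lay between the 1.5 set to argue against them and the 3 set to argue for them. Of the 16 with counts, 9 were highest in library 1 by depth-scaled expected counts, which met the other condition set, a majority. Among these 9, Hp had 8, 8 and 6 counts and was highest in library 2 by TPM (0.32, 0.37 and 0.20). The majority therefore depended on the measure. A source in granulocytes and chance sampling of few molecules both stay open, since counts were low and the list was 1 of 28 inspected.

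Ighm stood at 1630 ± 72.8 TPM, far above Cd79b at 29.3 ± 3.95 (SD, n = 3). Counts on Ighv segments were at most 1.06% of those on Ighm, which argues against B cells as the main source, whereas Igkv segments reached 25.1% ± 3.71 of Igkc and Trbv segments 23.4% ± 0.604 of the Trbc genes (SD, n = 3). Shared reads were argued against by whole Ighm counts and by at least 1.96 smaller-table counts per base. Transcription of the Ighm constant region without a rearranged variable segment is a hypothesis that remains open and was not tested. No biological explanation was tested against a second group.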

How the results depend on the processing

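Alternatives that kept only members with no shared reads, divided the chi-square by the overdispersion shared by all genes, or left out a library in the test of lists among varying genes, were chosen after seeing the data. The cause of the changes below was not tested, except where fewer genes or libraries entered. The coefficient of variation was 28.2% with no count filter, 11.7% from a summed count of 300, 8.87% in the smaller table, 8.05% as the DESeq2 gene-wise median, and 15.2% to 21.6% with each library left out. The 10471 varying genes became 3849 in the smaller table, 5953 with at least 10% excess, 328 with the chi-square divided by the shared overdispersion, and 5995 to 7268 with each library left out. The 3 lists or segment groups called among varying genes became 6 with at least 10% excess, where both segment groups stayed called. Treg activation was not called there and turned direction (3 of 23 members, Fisher's exact test, adjusted p = 0.0679). Treg core (0 of 16, adjusted p = 0.00957), naive and resting (0 of 14, 0.0125) and pan T cell genes (0 of 13, 0.0171) were under-represented, and granulocyte and mast cell genes (5 of 5, 0.035) over-represented. Excess variation was smaller in abundant genes, and this setting was not matched on mean count. The calls of these lists, and the turn of Treg activation, therefore cannot be told apart from an effect of abundance. With each library left out, 2 to 3 lists or segment groups were called. Suppressive mediators minus effector cytokines was 1.61 among members with a TPM of at least 1 and 2.29 among those with no shared reads. S phase minus mitosis was 0.90 in the smaller table and 2.04 with no shared reads. Activation minus naive was 0.22 by medians, and glycolysis minus oxidative phosphorylation was 0.47 with no length correction, neither past the threshold in any setting. The log2 ratio Foxp3/Gata3 was -0.71 with no length correction and -0.092 in the smaller table, where Il2ra/Il7r was -0.088 and Prdm1/Tcf7 0.20. The rank correlation of the 2 gene tables was 0.830 over detected genes. The gene pairs past the spread were 12 of 15 in the smaller table. Treg core minus helper factors was 1.56 there, still past the threshold. Under the alternatives, 55 list comparisons kept their direction and side of the threshold, and detection ranged from 9733 to 15361 genes. Glycolysis and the helper lineage transcription factors could not be compared among members with no shared reads, since 2 remained in each. Scarce genes rested on few counts, and the effect of depth on them was not tested.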

Other observations

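The genes in this part were chosen after their values were seen. Immunoglobulin constant regions differed between the libraries in different directions. Ighg1 had 359, 128 and 299 expected counts in libraries 1, 2 and 3, and Ighe had 50, 5 and 0. Ighg2b had 5.21, 219.7 and 147.8 and Ighg2c had 172.8, 6.28 and 287.2, with reads shared between similar genes. By contrast Ighd, with 366, 458 and 503 counts, and Ighm, with 52728, 51402 and 59974, were of similar size in each library. The mast cell protease gene Mcpt4 had 34 counts in library 3 and 0 in the other two.

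T cell receptor constant regions were steady. Trac stood at 2846 ± 8.80 TPM, Trbc2 at 3220 ± 14.8 and Trbc1 at 1464 ± 30.9 (SD, n = 3). Of 144 annotated T cell receptor V segments, 121 were detected in all libraries, against 5 of 218 immunoglobulin V segments. The ribosomal RNA gene CT010467.1 stood at 5677 ± 256 TPM and mitochondrial mt-Rnr2 at 3099 ± 399 (SD, n = 3).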
